A study of Homo sapiens with 7 samples.

How the data were processed

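RNA was measured by sequencing in 7 libraries of cultured human lung cells selected for PDGFRβ. Per the labels, 4 came from normal lung (NORML) and 3 from lung of systemic sclerosis with interstitial lung disease (SSCL). The cells grew on gelatin in a pericyte medium with little serum and had no treatment. Per the labels' protocols, total RNA was prepared with a Bio-Rad Aurum kit and DNase and made into libraries with the NEBNext Ultra RNA kit. Groups were taken from the disease state label. The labels do not tie libraries to cultures or people beyond naming them as separate samples, so the authors' p-values for single genes measure the spread between these samples.

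Per the submitters' processing notes, the tools were CASAVA, STAR, featureCounts, HTSeq and DESeq2, and the genome builds GRCh38 and hg38; their versions, settings and order are not given in the sources used here. The 1 file analysed holds the authors' comparison of SSCL with NORML, a DESeq2 results table per the file headers, with 19773 genes named by symbol. Its signal column is a mean over all libraries of normalized read counts, made by the authors before deposit. Its fold changes and their standard errors are on the log2 scale, as the authors deposited them. Its test score, the Wald statistic of the authors, equals the fold change divided by its standard error in every gene to within 5.7e-14. Its p-values are the two-sided normal p of that score, and the adjusted p-values the authors deposited equal a Benjamini-Hochberg adjustment over the 17349 genes that have one, to within 2.8e-15 and 3.1e-15. Of the rest, 123 genes had no p-value and 2301 had a p-value and no adjusted p, the latter with mean counts of 3.11 or less. The table has 1 comparison and no values per library.

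The design written before the data were examined gave a count test or a limma test for values per library, and the authors' adjusted p with a threshold of 0.05 for a table of the authors' comparison alone. The last applied. The depth per library is not known here, and no interval or floor that needs it is given. The direction of the fold changes is taken from the name of the comparison. Implied group means were computed from the mean count and the fold change, taking all 4 and 3 libraries as entering the mean, and are estimates.

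A total of 30 gene lists, covering cell type markers, matrix, signalling, stress and growth, was fixed before the data were examined. The lists hold 997 different genes, of which 875 were in the table. Each list with at least 5 tested members was tested with cameraPR (limma 3.58.1 in R 4.3.3) on the authors' score with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists tested. An estimated correlation needs values per library and was not computed. The cameraPR p-values for lists and families compare members' scores with those of other genes. They do not measure how well a list's shift repeats between samples. The median log2 fold change of each list was placed among those of 10000 random lists of the same size matched on mean count in 20 bins. Genes of the random lists were drawn independently, so they do not show the spread of lists whose members vary together. Members past the threshold were also counted with p-values adjusted over the list alone.

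Named genes were chosen by a rule written before the data were examined, leaving out XIST, Y chromosome genes, pseudogenes and genes with no symbol. It takes, among genes past the threshold with a mean count of at least 50, the 10 with the largest log2 fold change in each direction, then the 5 with the smallest adjusted p in each direction, up to 4 members of each described list with the smallest adjusted p, and PDGFRB. The genes named outside it were chosen after their values were seen. They are FN1, MCAM, MACF1, PDGFRA, CDH5, COL1A1, COL1A2, COL3A1, and those named from families, from lists added later and among genes with no p-value. Some genes the rule takes are not reported here.

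Gene positions, transcript lengths and GC content came from GENCODE v29, in which 19749 symbols were found and 24 were not. The principal transcript of each gene in APPRIS, or else the longest basic one, gave its length. The longest transcript of any kind was used first and replaced because, for ribosomal protein genes, it gave a median of 1917 bases against 1056. A smooth trend of log2 fold change on log2 length and GC content was fitted with mgcv 1.9.3 to 10857 genes with a mean of at least 50 that are in none of the 30 lists, weighted by the inverse squared standard error, and explained 10.3% of the deviance. It was then taken off the fold change of every gene and the p-values recomputed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

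The steps were tested on simulated data with known answers. With fold changes drawn for the 11555 genes of this comparison with a mean of at least 50 from their own standard errors, 37% of genes changed by 1 on the log2 scale and 86% of those changed by 2 were called, and 7.52% of called genes were unchanged. The draw takes the authors' standard errors as right. These shares therefore do not cover errors of the authors' count model or libraries that stand apart. Over 17349 simulated scores, drawn independently for each gene, lists with no shift were called in 0% of tests and lists shifted by 2 in 99.3%. The 0% therefore does not give the rate of false calls for lists whose members vary together. Reads shared with near-identical copies, such as those of AKR1C1 and AKR1C2, of SULT1A1 and its paralogs, or of keratin, histone and ribosomal protein genes with pseudogenes, could be split by the counting, so the values of these genes are uncertain. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

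The alternatives written before the data were examined were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, adjustment over every gene with a p-value, minimum mean counts of 10 and 50, protein-coding genes only, a preset correlation of 0.05, ranks, no filter on the mean, and centring on the median of all genes. Autosomal genes only and the removal of the length and GC trend were chosen after seeing the data.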

Results

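The series profiled RNA from human lung cells cultured as pericytes, the contractile cells that wrap the outside of small blood vessels. Cells from minced and digested lung tissue were grown in a low-serum pericyte medium and selected for PDGFRβ, the surface receptor for platelet-derived growth factor B. There were 7 libraries, 4 from normal lung (group NORML) and 3 from lung of people with systemic sclerosis and interstitial lung disease (group SSCL), a disease of scarring, vessel injury and autoimmunity. The values used here are the authors' own comparison of the groups for 19773 genes. Of the summed mean normalized counts of all genes, FN1, the gene for fibronectin, named after its value was seen, took 3.37% and the 10 highest genes together took 11.3%. The depth of each library is not known here, because the table gives means over libraries.

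The comparison of SSCL with NORML asks how lung cells cultured as pericytes differ between the disease and normal lung. In the authors' deposited table, 1304 of 17349 genes with an adjusted p were past 0.05, of which 774 were higher in SSCL and 530 lower. Of these, 673 higher and 429 lower genes had an absolute log2 fold change of at least 1. As sets, genes of the mesothelium, the lining of the pleura, genes that respond to interferon and cell cycle genes were higher, and lung fibroblast markers and cytosolic ribosomal protein genes were lower. Pericyte identity and interstitial matrix genes were also lower as sets and endothelial markers higher, but these 3 calls were lost with a preset correlation of 0.05 and with ranks. In each of these lists but the mesothelial one, most tested members did not pass on their own, and no cell cycle gene did. The direction, SSCL over NORML, rests on the name of the comparison alone, and no group means were used here that could check it.

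Among the genes open to the naming rule, which are past the threshold at a mean normalized count of at least 50, the largest rises were in CRISPLD1 and IQCA1, with log2 fold changes of 8.76 ± 1.91 and 8.68 ± 2.02 (authors' SE; adjusted p = 2.7e-04 and 8.7e-04) in the authors' deposited table. UPK1B and UPK3B, which encode uroplakins of urothelium and mesothelium, rose by 8.63 ± 1.61 and 8.56 ± 1.53 on the log2 scale (SE; adjusted p = 9.7e-06 and 2.9e-06) in the authors' deposited table. The gene UPK3B lies on chromosome 7 from 76510428 to 76516521 (GRCh38, GENCODE v29), and all gene positions given here are from that annotation. The same table of the authors, their deposited table, put WNT4, a secreted WNT ligand, at 8.17, DSC2, a desmosomal cadherin, at 8.09, LRRN4 at 7.67, PKHD1L1 at 7.32, CD38, an enzyme that consumes NAD, at 7.30 and CRB2, an apical polarity protein, at 7.12. The standard errors of these 6 genes in the authors' deposited table ran from 1.14 for PKHD1L1 to 2.41 for DSC2. The largest adjusted p among them was 0.017, for DSC2.

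By the same rule the largest falls were in ADH1B, an alcohol dehydrogenase, and APCDD1, a membrane inhibitor of WNT signalling, at log2 fold changes of -9.56 ± 1.56 and -9.37 ± 2.15 (authors' SE; adjusted p = 1.6e-07 and 6.9e-04) in the authors' deposited table. ADH1B lies on chromosome 4 from 99304964 to 99352760. In the authors' deposited table the collagen genes COL21A1 and COL15A1 stood at -7.38 ± 1.49 and -7.02 ± 1.86, the scavenger receptor gene SCARA5 at -6.99 ± 1.83 and the fatty acid binding protein gene FABP4 at -6.31 ± 1.04 (SE). CHRDL1, which encodes a secreted BMP antagonist, stood at -6.23 ± 0.69, the complement gene C7 at -6.16 ± 1.38, CRABP2, for a retinoic acid binding protein, at -5.64 ± 0.60 and CLEC3B, for tetranectin, at -5.45 ± 0.91 in the authors' deposited table. Of the 10 largest rises by the rule, 3 (CRISPLD1, IQCA1 and DSC2) had an implied NORML mean under 1 normalized count, and of the 10 largest falls, 3 (APCDD1, COL21A1 and SCARA5) had an implied SSCL mean under 1, so these folds are loosely set.

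The smallest adjusted p among genes that rose in the authors' deposited table belonged to IFI27, an interferon-induced gene on chromosome 14 from 94104836 to 94116698, at a log2 fold change of 6.13 ± 0.55 (authors' SE; adjusted p = 3.3e-24). Among the next in the authors' deposited table were ADAMTS9, a secreted metalloprotease (5.63 ± 0.54), SULT1A1, a sulfotransferase (4.41 ± 0.43), and CDH2, the N-cadherin gene (4.43 ± 0.44). Among genes that fell, COL7A1, for the collagen of anchoring fibrils, had the smallest adjusted p, at -4.20 ± 0.39 (SE; adjusted p = 4.5e-23) in the authors' deposited table. COL7A1 lies on chromosome 3 from 48564073 to 48595267. CRABP2, SYT7, a calcium sensor of vesicle fusion (-3.54 ± 0.38), CHRDL1 and GRIA1, a glutamate receptor subunit (-5.31 ± 0.60), came next in the authors' deposited table.

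**Figure D1:**
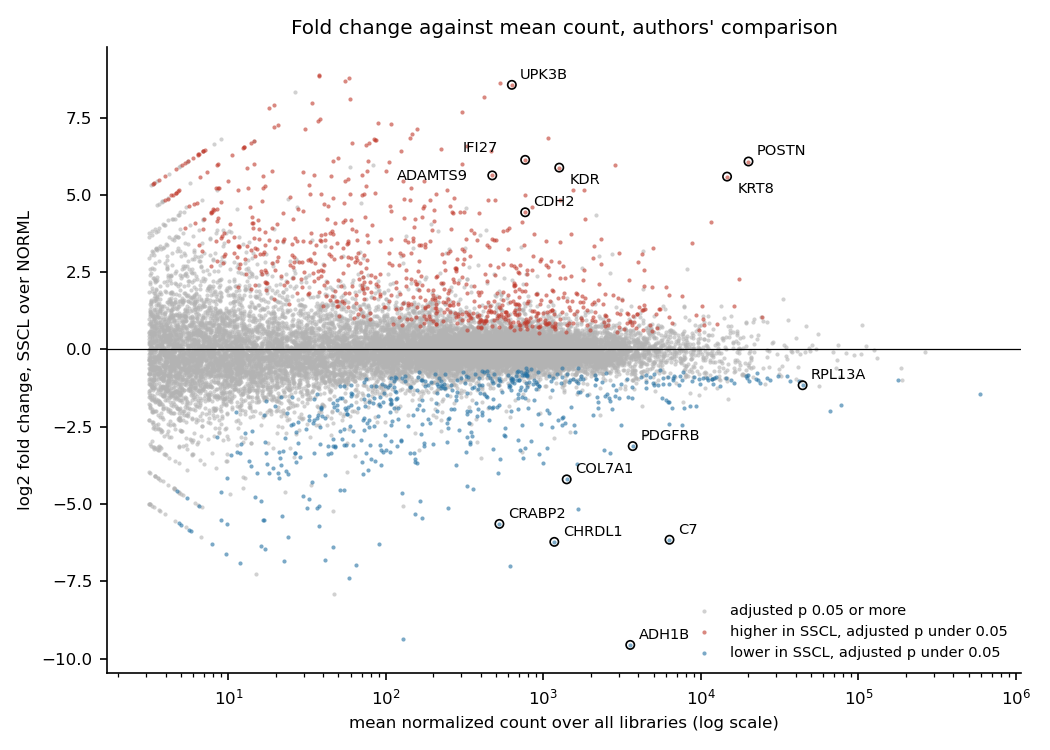
Each point is a gene (XIST and Y chromosome genes are not drawn), with its mean normalized count over all libraries on a log scale (x) and its log2 fold change, SSCL over NORML (y), from the authors' deposited table. Red and blue points are past an adjusted p of 0.05, and the circled genes are named in the text, from ADH1B at -9.56 to UPK3B at 8.56.

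**Figure D2:**
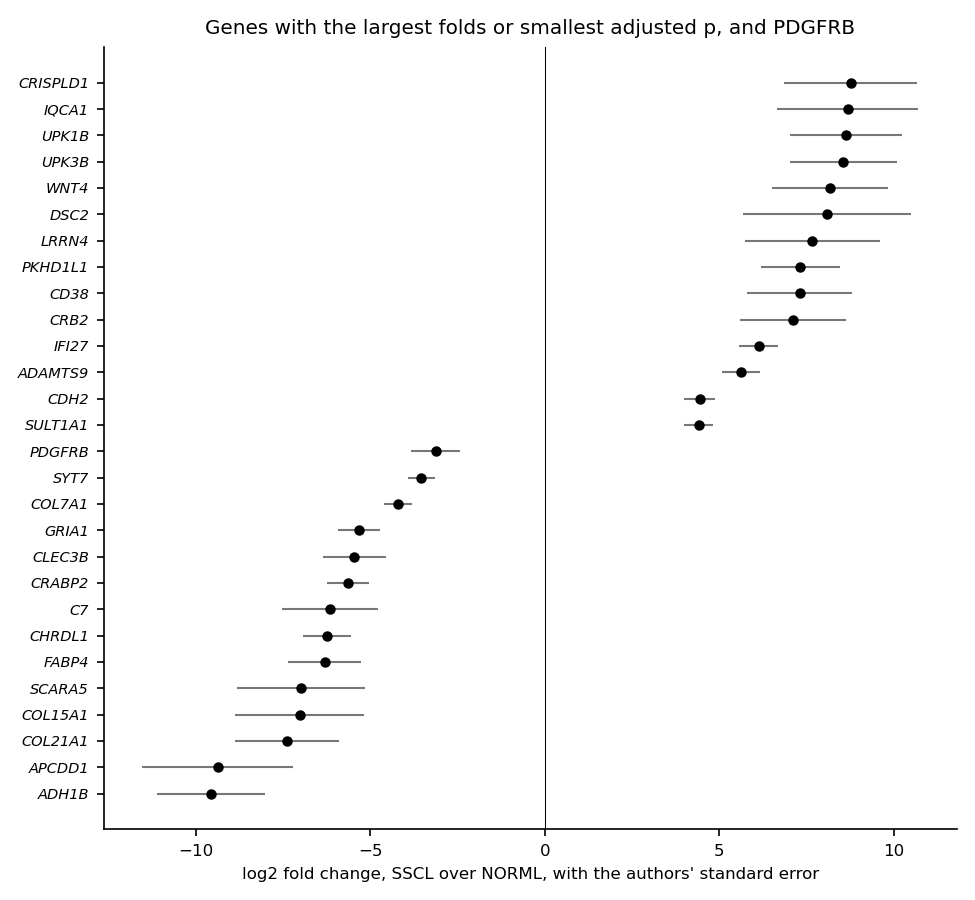
Log2 fold change, SSCL over NORML (x), of genes with the largest folds or the smallest adjusted p and of PDGFRB, from the authors' deposited table. Points are the authors' estimates and bars their standard errors; no bar reaches 0.

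PDGFRB, the gene of the receptor the cells were selected for, fell by 3.13 ± 0.69 on the log2 scale (SE; adjusted p = 3.9e-04) in the authors' deposited table. It lies on chromosome 5 from 150113837 to 150155872. With 4 and 3 libraries in the groups, its fold and its mean of 3689 imply about 5945 normalized counts in NORML and 680 in SSCL. Of 12 tested pericyte identity genes, 4 fell, 1 rose and 7 did not pass (5 fell and 1 rose adjusted over the list alone). Besides PDGFRB the genes that fell in the authors' deposited table were CD248, endosialin (-1.84 ± 0.43), NDUFA4L2, a mitochondrial protein of pericytes (-3.53 ± 0.89), and KCNJ8, a potassium channel subunit (-2.20 ± 0.69, SE). The 1 that rose was the adhesion molecule gene MCAM (2.36 ± 0.77, SE) in the authors' deposited table, named after its value was seen. The list was lower as a set (cameraPR adjusted p = 0.043), but not with a preset correlation of 0.05 (adjusted p = 0.11) or with ranks (adjusted p = 0.19). The list's median was -0.64, beside a median of 4.46 for mesothelial markers in the same comparison.

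Mesothelial markers rose together: 10 of 16 tested members rose, none fell and 6 did not pass (12 rose adjusted over the list alone), with a median log2 fold change of 4.46 and a cameraPR adjusted p of 4.1e-14. PKHD1L1, UPK3B, UPK1B and BNC1, a zinc finger gene of mesothelium and some epithelia (3.54 ± 0.70, SE), had the smallest adjusted p of the list in the authors' deposited table. KRT8 and KRT18, keratins of simple epithelia and mesothelium, are also in this list. The epithelial list had 3 of 11 members higher, none lower and 8 not past the test (3 rose and 1 fell adjusted over the list alone; cameraPR adjusted p = 0.15). The 3 were KRT8 (5.59 ± 1.21), KRT18 (4.12 ± 1.25) and KRT7 (5.15 ± 1.73, SE) in the authors' deposited table, and KRT8 had a mean of 14654 normalized counts. SFTPB, a surfactant protein gene of alveolar epithelium, did not pass, at -3.66 ± 1.38 (SE; adjusted p = 0.082) in the authors' deposited table. Of the 18 mesothelial genes, 2 had no p-value and are not among the tested members. They were KRT19 (2.40 ± 1.37) and PDPN (0.51 ± 1.64, SE) in the authors' deposited table, with means of 8178 and 1441 normalized counts.

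Lung fibroblast markers were lower as a set (cameraPR adjusted p = 4.7e-06; median -1.41), with 8 of 22 tested members lower, 1 higher and 13 not past the test (10 fell and 1 rose adjusted over the list alone). In the authors' deposited table GPM6B (-3.18 ± 0.37), FGFR4, a fibroblast growth factor receptor (-3.63 ± 0.56), ADH1B and TCF21, a transcription factor of lung mesenchyme (-2.80 ± 0.54, SE), had the smallest adjusted p. The 1 member that rose was MACF1, a cytoskeletal linker (0.97 ± 0.28, SE) in the authors' deposited table, named after its value was seen. PDGFRA, also of this list and named after its value was seen, did not pass (-0.29 ± 0.63, SE, adjusted p = 0.87) in the authors' deposited table. Its mean was 3234 normalized counts. Mesothelial markers, whose median was 4.46, rose in the same comparison. Whether both changes occurred in the same libraries was not tested.

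Endothelial markers were higher as a set at a cameraPR adjusted p of 0.046 (median 0.58, beside 4.46 for mesothelial markers in the same comparison), from 10 tested members of which 2 rose, 1 fell and 7 did not pass (3 rose and 1 fell adjusted over the list alone). KDR, the main endothelial VEGF receptor (5.88 ± 0.78), and TEK, the angiopoietin receptor (3.0 ± 0.74), rose and CLEC14A, an endothelial lectin (-3.01 ± 0.85, SE), fell in the authors' deposited table, while TIE1 did not pass (2.94 ± 1.11, SE; adjusted p = 0.085). KDR, TEK and TIE1 are also in the vascular remodelling list. The cadherin gene CDH5 did not pass (1.14 ± 1.52, SE, adjusted p = 0.77, mean count 3.19), and ESAM had no p-value (-3.23 ± 1.27, SE) in the authors' deposited table. The call on the endothelial list was lost with a preset correlation of 0.05 (adjusted p = 0.11) and with ranks (0.19). It was also lost with no filter on the mean (0.11) and with fold changes centred on the median of all genes (0.058). Of 9 neural and glial markers, 1 rose (ERBB3, a neuregulin receptor, 4.07 ± 1.06, SE) and 1 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.92). Leukocyte markers had 4 tested members, too few for a list test, and none passed, over all genes or adjusted over the list alone (2 had an unadjusted p under 0.05); CD74 stood at 1.45 ± 0.63 and CD14 at 1.74 ± 0.89 (SE) in the authors' deposited table. CD74 passed with the trend of fold change on transcript length and GC content taken off (1.85; adjusted p = 0.049), an alternative chosen after seeing the data.

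Interferon response genes were higher as a set (cameraPR adjusted p = 1.4e-11; median 1.14). Of 33 tested members 9 rose, none fell and 24 did not pass, and 15 rose adjusted over the list alone. The leading genes in the authors' deposited table were IFI27, MX1, an antiviral GTPase (4.44 ± 0.70), IFI6 (2.73 ± 0.57) and OAS3, an oligoadenylate synthetase (2.71 ± 0.60, SE). A positive fold change was listed for 31 of the 33 genes. The mesothelial markers, with a median of 4.46, rose in the same comparison.

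Inflammatory mediators did not pass as a set (cameraPR adjusted p = 0.88). Of 35 tested, 2 rose, 2 fell and 31 did not pass (3 rose and 5 fell adjusted over the list alone). ICAM1, a leukocyte adhesion molecule (3.11 ± 0.33), and IL1B, a pyrogenic cytokine (5.20 ± 1.4), rose, and TSLP, an epithelial-type cytokine (-3.08 ± 0.58), and the chemokine gene CCL13 (-5.52 ± 1.51, SE) fell in the authors' deposited table. IL1B and CCL13 had means of 8.56 and 8.95 normalized counts. Of 17 complement genes, 1 rose (C3, 2.58 ± 0.77, SE, in the authors' deposited table), 1 fell (C7) and 15 did not pass (5 rose and 4 fell adjusted over the list alone; cameraPR adjusted p = 0.55).

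Interstitial matrix genes were lower as a set (cameraPR adjusted p = 7.8e-03; median -0.68), with 11 of 36 lower, 3 higher and 22 not past the test (14 fell and 4 rose adjusted over the list alone). The proteoglycan gene BGN (-2.92 ± 0.45) and the collagen genes COL16A1 (-2.81 ± 0.56) and COL5A3 (-3.55 ± 0.80, SE) fell in the authors' deposited table. Against that direction POSTN, periostin, rose by 6.08 ± 1.49 on the log2 scale (SE; adjusted p = 1.9e-03) in the authors' deposited table, at a mean of 20045 normalized counts. POSTN lies on chromosome 13 from 37562583 to 37598844. The set call was lost with a preset correlation of 0.05 (adjusted p = 0.11) and with ranks (adjusted p = 0.11). Mesothelial markers rose in the same comparison (median 4.46), and whether in the same libraries was not tested.

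Basement membrane genes did not pass as a set (cameraPR adjusted p = 0.85). Of 20 tested, 1 rose, 3 fell and 16 did not pass (3 rose and 4 fell adjusted over the list alone). The laminin gene LAMA3 rose (2.85 ± 0.60) and LAMC3 (-5.12 ± 0.90), NID2 (-1.71 ± 0.50) and NID1 (-2.42 ± 0.79, SE), for laminin and nidogens, fell in the authors' deposited table. Of 27 matrix proteases and inhibitors, 3 rose, 4 fell and 20 did not pass (5 rose and 5 fell adjusted over the list alone; cameraPR adjusted p = 0.61). ADAMTS9, ADAM19 (2.46 ± 0.37) and MMP24 (3.17 ± 0.50) rose, and PLAU, the urokinase gene (-3.19 ± 0.45, SE), fell in the authors' deposited table. Of 19 contractile and smooth muscle genes, 1 rose (TPM1, tropomyosin, 2.05 ± 0.56) and 1 fell (LMOD1, leiomodin, -2.38 ± 0.48, SE) in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.94). The contractile genes ACTG2 (-2.64 ± 1.31; adjusted p = 0.24) and SMTN (-0.67 ± 0.44; adjusted p = 0.43) did not pass in the authors' deposited table.

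The series text names 4 pathways, and the lists written for them are therefore not independent evidence of a change. None of the 4 passed as a set. The cameraPR adjusted p was 0.55 for prostaglandin, 0.94 for PI3K-Akt core, 0.67 for calcium signalling and 0.92 for vascular remodelling genes. That test looks for a net shift in one direction, so genes moving both ways can cancel. Over all tested genes, 7.52% passed singly. The shares among prostaglandin, calcium signalling and vascular remodelling genes were above that, and the share among PI3K-Akt genes was near it. Whether these shares differ from that of all genes was not tested. Of 29 prostaglandin genes, 2 rose, 5 fell and 22 did not pass (4 rose and 8 fell adjusted over the list alone). PTGS1, the constitutive cyclooxygenase (-2.68 ± 0.63), the aldo-keto reductases AKR1C1 (-2.43 ± 0.53) and AKR1C2 (-2.24 ± 0.60) and the prostaglandin receptor gene PTGDR2 (-4.00 ± 1.07, SE) fell in the authors' deposited table. Of 42 PI3K-Akt genes, 2 rose, 1 fell and 39 did not pass, with the same counts adjusted over the list alone. The kinase gene SGK1 (2.76 ± 0.67) and the phosphatase gene PHLPP1 (1.05 ± 0.32) rose, and the cyclin gene CCND2 (-1.57 ± 0.32, SE) fell in the authors' deposited table.

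Of 72 calcium signalling genes, 5 rose, 10 fell and 57 did not pass (7 rose and 11 fell adjusted over the list alone). BDKRB2, a bradykinin receptor (-2.44 ± 0.37), the store-operated channel gene ORAI3 (-1.47 ± 0.31) and the adrenergic receptor gene ADRA1D (-2.72 ± 0.74) fell, and the kinase gene CAMK2A (3.70 ± 0.99, SE) rose in the authors' deposited table. Of 61 vascular remodelling genes, 8 rose, 6 fell and 47 did not pass (10 rose and 10 fell adjusted over the list alone). KDR and the neuropilin gene NRP2 (2.57 ± 0.45) rose, and NPR3, the natriuretic peptide clearance receptor (-3.21 ± 0.44), and STC1, stanniocalcin (-3.68 ± 0.52, SE), fell in the authors' deposited table.

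Of 43 TGF-β and BMP signalling genes, 5 rose, 4 fell and 34 did not pass (7 rose and 5 fell adjusted over the list alone; cameraPR adjusted p = 0.63). BMP4 (4.23 ± 0.67), the receptor decoy BAMBI (3.83 ± 0.74) and SKIL, a repressor of SMAD signalling (1.52 ± 0.34), rose, and LTBP1, which binds latent TGF-β (-1.19 ± 0.26, SE), fell in the authors' deposited table. Of 29 WNT signalling genes, 3 rose, 4 fell and 22 did not pass (7 rose and 6 fell adjusted over the list alone; cameraPR adjusted p = 0.94). SFRP4, a secreted WNT antagonist (4.50 ± 0.77), rose, and WISP2 (-5.12 ± 0.91), WNT5B (-1.93 ± 0.48, SE) and APCDD1 fell in the authors' deposited table. Of 41 growth factors and receptors, 3 rose, 4 fell and 34 did not pass (5 rose and 6 fell adjusted over the list alone; cameraPR adjusted p = 0.81). PDGFD, a ligand of PDGFRβ (3.86 ± 0.59), rose, and FGFR4, PDGFRB and EREG, epiregulin (-2.46 ± 0.55, SE), fell in the authors' deposited table. Of 41 positional transcription factors, 3 rose, 2 fell and 36 did not pass (4 rose and 8 fell adjusted over the list alone; cameraPR adjusted p = 0.69). TBX2 (-3.34 ± 0.51) and TCF21 fell, and MEIS2 (1.76 ± 0.32) and GATA6 (2.12 ± 0.57, SE) rose in the authors' deposited table.

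Cell cycle genes were higher as a set (cameraPR adjusted p = 2.5e-04; median 0.87), with a positive fold change for 39 of 40 genes, beside a median of 4.46 for mesothelial markers in the same comparison. No member passed the authors' test on its own, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. The leading ones in the authors' deposited table were CDC6, a replication licensing factor (1.52 ± 0.65; adjusted p = 0.14), CCNE1 (0.60 ± 0.29; 0.22), KIF23 (1.12 ± 0.55; 0.24) and CCNB1 (1.10 ± 0.54, SE; 0.24). Of 22 p53 and senescence genes, 1 rose, 2 fell and 19 did not pass, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.88). CDKN2B, a cell cycle inhibitor (-1.0 ± 0.32), and BBC3, a pro-apoptotic gene (-1.25 ± 0.42), fell and TNFRSF10B, a death receptor (0.62 ± 0.20, SE), rose in the authors' deposited table. Of 31 immediate early and stress genes, 1 rose, 3 fell and 27 did not pass, again with the same counts adjusted over the list alone (cameraPR adjusted p = 0.073). NR4A2, a nuclear receptor (-3.34 ± 0.61), KLF4 (-2.01 ± 0.50) and IER2 (-0.70 ± 0.22) fell and TXNRD1, thioredoxin reductase (1.4 ± 0.29, SE), rose in the authors' deposited table. With the length and GC trend taken off, BBC3 (-0.85 ± 0.42; adjusted p = 0.28), TNFRSF10B (0.53 ± 0.20; 0.095) and IER2 (-0.56 ± 0.22, SE; 0.11) did not pass, since the folds shrank and the authors' standard errors were kept.

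Cytosolic ribosomal protein genes were lower as a set (cameraPR adjusted p = 1.5e-21; median -0.87), with a negative fold change for all 52. In the same comparison mesothelial markers (median 4.46) and cell cycle genes (median 0.87) were higher as sets. Of the 52 ribosomal protein genes, 23 fell and 29 did not pass, and 49 fell adjusted over the list alone. RPS18 (-1.09 ± 0.30), RPL13A (-1.16 ± 0.34), RPL10A (-0.97 ± 0.28) and RPL7A (-1.0 ± 0.30, SE) had the smallest adjusted p of the list in the authors' deposited table. With the trend of fold change on transcript length and GC content taken off, the set was still lower (adjusted p = 7.2e-13; median -0.58), but 5 single genes passed and these 4 did not, as their folds shrank to between -0.61 (RPL10A) and -0.90 (RPL13A) at the same standard errors. Many ribosomal protein genes have processed pseudogenes that can share their reads.

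The lists of cholesterol and sterol synthesis (26 genes), mitochondrially encoded genes (15) and replication-dependent histones (12) had no member past the test, over all genes or adjusted over the list alone, and cameraPR adjusted p of 0.88, 0.88 and 0.61. Their leading members in the authors' deposited table were FADS1, a fatty acid desaturase (-1.29 ± 0.70; adjusted p = 0.30), the mitochondrial ribosomal RNA gene MT-RNR1 (-0.70 ± 0.57; 0.57) and HIST1H2AC (-0.81 ± 0.44, SE; 0.30). At an unadjusted p under 0.05 the authors' test also passed 0 genes of each of these 3 lists. Of 27 hypoxia and glycolysis genes, 1 fell and 26 did not pass, with the same count adjusted over the list alone (cameraPR adjusted p = 0.92). That gene was PFKFB4, a regulator of glycolysis (-1.64 ± 0.43, SE), in the authors' deposited table, while LDHA did not pass (0.40 ± 0.23; adjusted p = 0.34).

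In all, 8 of 29 lists passed cameraPR, 4 higher and 4 lower, and 5 passed with a preset correlation of 0.05 or with ranks. In 7 lists the sign of the median, of the mean or of the test differed from the others: contractile, matrix protease, PI3K-Akt, calcium, vascular remodelling, inflammatory and positional transcription factor genes. A further 5 lists that did not pass had medians outside the central 95% of random lists matched on mean count, namely growth factors, complement and epithelial markers above it and immediate early genes and histones below it.

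**Figure D3:**
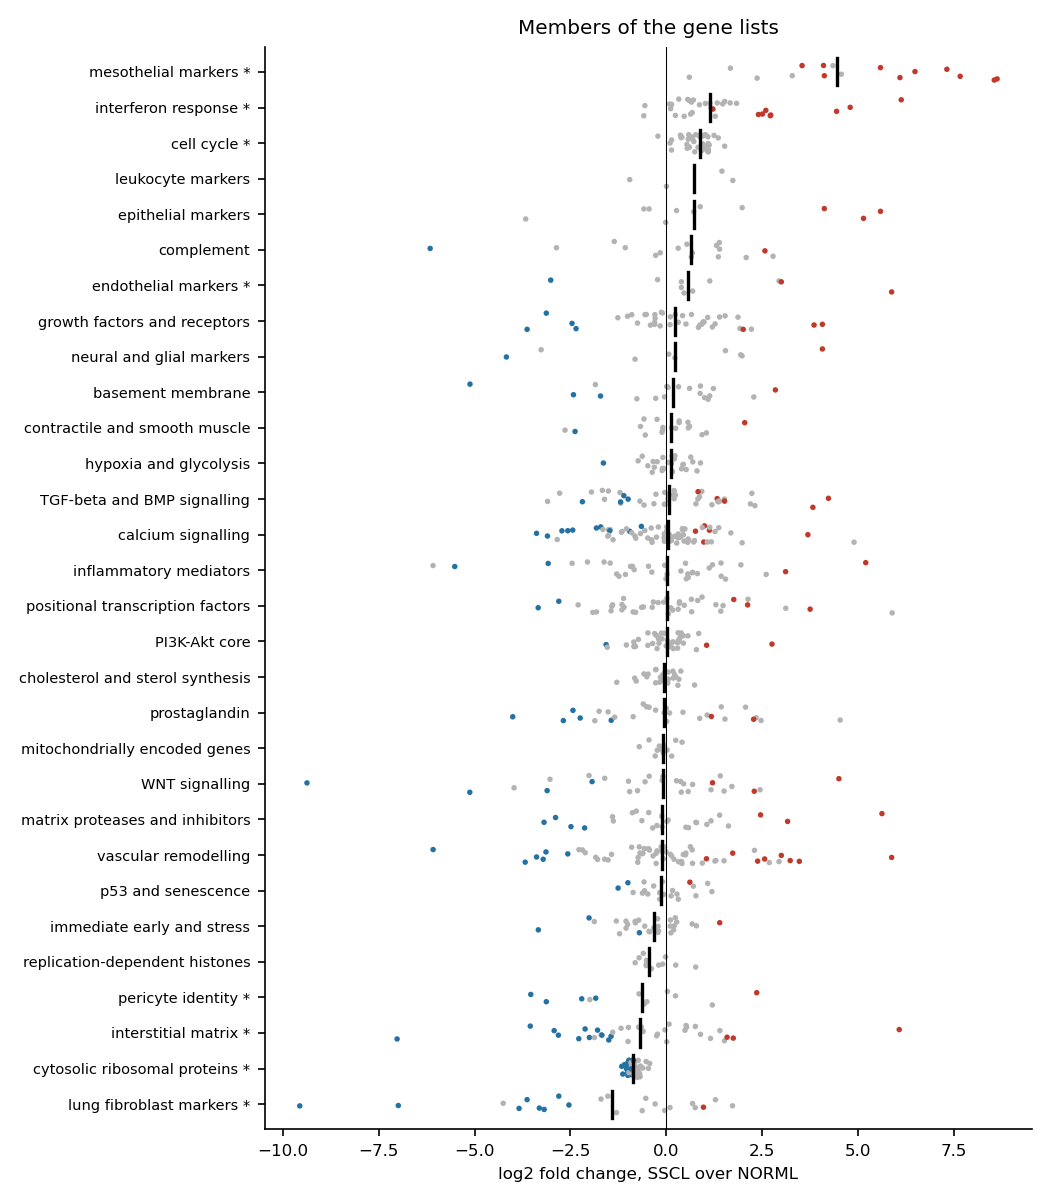
Each point is a tested member of a gene list, at its log2 fold change, SSCL over NORML (x), in the authors' deposited table; red and blue points are past an adjusted p of 0.05, and black bars are list medians. Asterisks mark the 8 lists past a cameraPR adjusted p of 0.05, with medians from -1.41 for lung fibroblast markers to 4.46 for mesothelial markers.

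Fold changes also followed the length and base composition of transcripts. Across 11536 genes with a mean of at least 50, the log2 fold change in the authors' deposited table had a Spearman rho of 0.292 with transcript length and of -0.227 with GC content. Genes are not independent replicates, so no p is given for either. The median log2 fold change was -0.34 in the group of genes with the shortest transcripts and 0.20 in that with the longest, of 8 groups of near equal size. With this trend taken off, 1168 genes passed, of which 1046 were among the 1304.

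**Figure D4:**
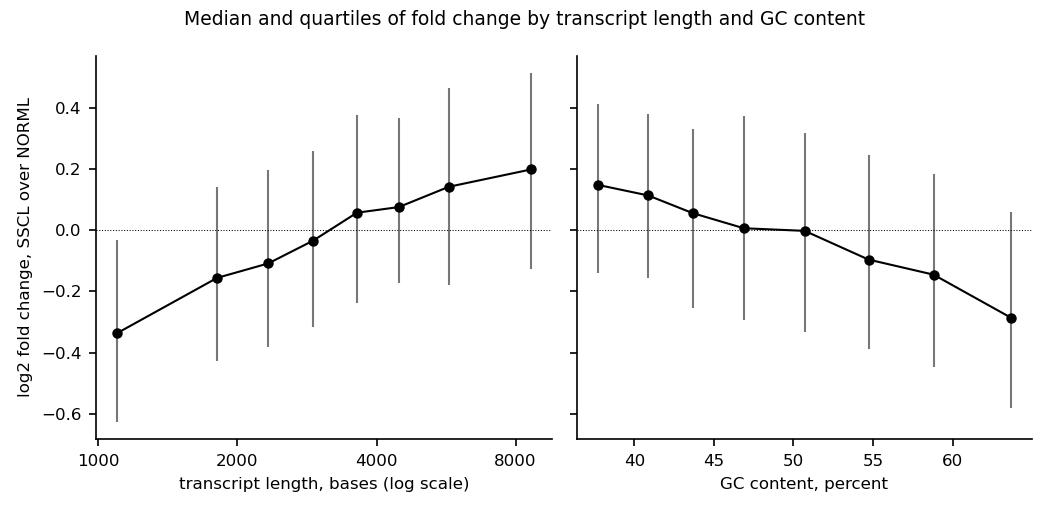
Median log2 fold change, SSCL over NORML (y), of 8 groups of genes by transcript length in bases on a log scale (left) and by GC content in percent (right), from the authors' deposited table. Points are medians and bars run between quartiles; medians go from -0.34 to 0.20 with length and from 0.15 to -0.29 with GC content.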

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

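The authors' deposited table gives 123 genes a fold change and no p-value, and the comparison above leaves them out. Among these, 26 had a statistic at least as large as the smallest of a gene past the threshold, 2.90. The 5 with the largest statistics in the authors' deposited table, chosen after their values were seen, were NPPB, the gene of B-type natriuretic peptide, RSAD2, an antiviral interferon-induced gene, the collagen gene COL14A1, the metalloprotease gene ADAMTS8 and the antisense transcript ROR1-AS1. Their log2 fold changes were 8.95 ± 1.28 for NPPB, 8.34 ± 1.48 for RSAD2, -4.48 ± 0.82 for COL14A1, -6.97 ± 1.35 for ADAMTS8 and 5.44 ± 1.10 for ROR1-AS1 (authors' SE) in the authors' deposited table. Reads of ROR1-AS1 and of the gene on the other strand cannot be told apart, since the strand setting is not known here. The median standard error of the 123 genes was 1.49, against 0.49 for random lists matched on mean count. A fold change above 0 was listed for 40 of them and below 0 for 83, and 23 are in a gene list. DESeq2, used by the authors, withholds a p-value by default where a single count stands far from the fit; whether that applied to each gene is not recorded in the sources used here.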

How the results depend on the processing

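The counts of 1304 genes, 774 higher and 530 lower, moved by more than 1.5 times under 1 alternative, an adjusted p under 0.01 (701 genes, 456 higher and 245 lower), which follows from the stricter threshold. Under the other alternatives the total ran from 1041 (mean count at least 50) to 1836 (adjusted p under 0.1). Of 29 lists, 8 passed, and 5 passed with a preset correlation of 0.05 and 5 with ranks. With the larger correlation, pericyte identity, interstitial matrix and endothelial markers each had an adjusted p of 0.111, from the wider variance alone. With ranks it was 0.190 for pericyte identity and endothelial markers and 0.114 for interstitial matrix, and the cause was not tested. Endothelial markers also missed the threshold with no filter (0.109) and with centring (0.0584), and epithelial markers passed at a mean of at least 50 (0.0185); the cause was not tested. At that mean, endothelial and neural markers had under 5 members and no value. The direction turned in lists that passed under no setting, and the cause was not tested: contractile (0.965) and growth factor genes (0.921) at a mean of at least 50, PI3K-Akt (0.975) and WNT genes (0.975) with ranks, and, with the length and GC trend taken off, contractile (0.963), basement membrane (0.963), vascular remodelling (0.872) and mitochondrially encoded genes (0.633). Mesothelial, interferon, lung fibroblast, cell cycle and ribosomal protein lists kept direction and call under every alternative run. All of these alternatives start from the same deposited comparison, and the largest correlation tried was 0.05. They therefore cannot show whether variation shared by the members of a list made its call. Of 136 named genes, 7 lost the call and 1 gained it with the trend taken off, an alternative chosen after seeing the data, as was autosomal genes only. Adjustment over every gene with a p-value changed the call of none of the 136. Other normalizations, tools, pseudocounts and filters on counts, leaving out each replicate, and other splits of the samples need values per library and were not run. No paired analysis was possible because the labels pair no samples and the table has no values per library. Depth per library is not known here, so what it limits was not assessed.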

Other observations

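Gene families, grouped only by the letters that start their symbols, can hold genes of other kinds. They were compared after the data had been seen, with 91 families of at least 15 genes tested by cameraPR on the score of the authors' deposited table, of which 11 passed, the RPL and RPS groups included; RPS also holds S6 kinase genes. Genes named from families were chosen after their values were seen. Cadherin genes (CDH) were higher as a family (adjusted p = 1.6e-03; median log2 fold change 1.53), with 5 of 15 higher and 1 lower, beside a rise of mesothelial markers (median 4.46) in the same comparison. Besides CDH2, they include CDH6 (4.20 ± 1.17), CDH3 (3.25 ± 1.02) and CDH4 (1.53 ± 0.49, SE) in the authors' deposited table, while CDH24 fell (-0.93 ± 0.30). Semaphorin genes (SEMA), which guide axons and vessels, were higher (adjusted p = 6.8e-03; median 0.42), with 5 of 18 higher and none lower. SEMA6B (4.43 ± 0.64), SEMA6A (3.97 ± 0.67) and SEMA4D (3.10 ± 0.59, SE) led in the authors' deposited table. TNF receptor genes (TNFRSF) were higher (adjusted p = 0.042; median 0.48), with 5 of 17 higher, among them TNFRSF9 (7.38 ± 1.13) and TNFRSF8 (2.79 ± 0.60, SE) in the authors' deposited table, and TNFRSF1B lower (-1.04 ± 0.28). Genes with symbols in KIF, kinesins and the kinesin-binding protein gene KIF1BP, were higher (adjusted p = 6.3e-04; median 0.71) with 2 of 33 past the test (some are in the cell cycle list), KIF21A (1.42 ± 0.34) and KIF21B (2.72 ± 0.69, SE) in the authors' deposited table.

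Mitochondrial ribosomal protein genes were lower as families, with an adjusted p of 1.2e-03 for 49 MRPL genes (median -0.36) and 0.027 for 29 MRPS genes (median -0.28), as were 22 COX genes (0.039; median -0.41). With the length and GC trend taken off, their adjusted p were 0.23, 0.22 and 0.23 and their medians -0.14, -0.13 and -0.15, so these calls ended because the medians shrank. The quartiles of MRPL genes went from -0.49 and -0.23 to -0.30 and -0.018, those of MRPS genes from -0.48 and -0.17 to -0.27 and -0.065, and those of COX genes from -0.53 and -0.28 to -0.29 and -0.065. KIAA genes were higher (adjusted p = 3.3e-03; median 0.26, quartiles -0.0027 and 0.69) and missed the threshold with the trend taken off (0.10; median 0.14, quartiles -0.13 and 0.63). ARHGEF genes were higher at an adjusted p of 0.039 and stood at 0.12 with the trend taken off. Their median moved only from 0.36 (quartiles -0.13 and 0.97) to 0.33 (quartiles -0.16 and 0.95), so the lost call does not show the trend to be its source. The cadherin, semaphorin, TNF receptor and KIF families stayed past the threshold (4.6e-03, 0.016, 0.013 and 0.011). Genes with symbols in COL, which are collagens, some of them in the interstitial matrix list, and the ceramide transfer gene COL4A3BP, gained a call as lower (adjusted p 0.087 before and 0.020 after) at medians of -0.60 and -0.55 over 37 genes.

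In the weighing that follows, the tests on lung epithelial transcripts, on uneven levels and without IFI27 and MX1 were chosen after the result was seen. The rise of mesothelial markers in SSCL is set first against the length and GC trend: with it taken off, the list median was 4.75 (4.46 before) and the adjusted p 7.2e-15, so the trend is not the whole source. This outcome was near certain beforehand. Medians of gene groups ran only from -0.34 to 0.20 with length and from 0.15 to -0.29 with GC content. Lung epithelial cells are argued against as the source, since of 21 listed lung epithelial transcripts 9 were in the authors' deposited table, and the highest of these, KRT15, had a mean count there of 76.6, 0.522% of that of KRT8. Cells of mesothelial lineage among the SSCL cultures are a candidate source: a second list of 15 mesothelial genes, with none of the first, had a median of 1.06 over 11 tested members, 4 of them higher (KLK11, BCHE, EZR and SULF1, named, as was KRT15, after their values were seen), above 100% of 10000 matched random lists. That median was well below the 4.46 of the first list, and the other tested members did not pass. Random lists of independently drawn genes are also a lenient standard for markers that vary together. Selection for PDGFRβ would be set against mesothelial cells, while the lower PDGFRB in SSCL does not argue against them. Lung fibroblast markers were lower as a set, with 8 of 22 lower, 1 higher and 13 not past the test. PDGFRA, among those 13, stood at -0.29 ± 0.63 (SE) in the authors' deposited table. The tissue expresses some of the mesothelial genes in other cells too, EZR (mean count 8716) and SULF1 (3996, in the authors' deposited table) among them. An uneven level between libraries cannot be told apart from a shift of the group. The markers' median standard error of 1.47 lay above 94.0% of lists matched on count and fold. KRT19 and PDPN, the 2 markers with no p-value, may each hold a single count far from the fit, which is not recorded. A change of the pericytes themselves in the disease stays open and untested.

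The fall of ribosomal protein genes was not matched by other genes of their length, GC content and mean count: 39 of them with enough matches had a median of -0.87, against -0.15 for matched random lists, of which 0 of 10000 (0%) were as low. The trend is therefore not the whole source, though it accounts for part, as the list median was -0.58 with it taken off. A shift shared with other short abundant housekeeping transcripts may contribute: 70 nuclear genes of oxidative phosphorylation had a median of -0.44 (quartiles -0.66 and -0.32), which is 50.7% of the ribosomal median and just past the bound of 0.5 set before. With the trend taken off, the median of these 70 genes was -0.21 against -0.58 for the ribosomal list, which misses that bound. The pass therefore does not show a shared shift apart from the trend. Cell cycle genes were higher as a set in the same comparison (median 0.87, cameraPR adjusted p = 2.5e-04). That is not the direction expected if slower growth lowered the ribosomal genes. No cell cycle gene passed on its own, and the correlation between members was preset and not estimated, so the set call does not settle growth state. Whether growth state, RNA quality or the disease itself lowered the ribosomal genes was not tested.

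The rise of interferon response genes stayed with the length and GC trend taken off (adjusted p = 9.2e-13) and without IFI27 and MX1 (adjusted p = 1.0e-07), so neither the trend nor these 2 genes is the whole source. Mesothelial markers rose in the same comparison (median 4.46), so which cells carry the interferon response is open. Interferon signalling in the SSCL cultures is a candidate explanation, as a hypothesis found and tested on the same data. Whether 1 culture carries the rise was not tested, since that needs values per library.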
